A study of Homo sapiens with 32 samples.

How the data were processed

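RNA of 32 samples of human H1 embryonic stem cells (hESC) and their differentiated progeny was measured on Illumina expression BeadChips, with 4 arrays in each of 8 groups. Per the labels, the groups are undifferentiated hESC (day 0), definitive endoderm (day 2), liver bud progenitors (day 6) and 5 groups of hepatic progenitors at day 12. The day 12 groups are the full base condition and the base condition without the Notch inhibitor DAPT, without forskolin, without AAP or without insulin. AAP was taken as ascorbic acid-2 phosphate, the only agent of the protocol with these initials. Per the labels' protocols the base medium of days 7 to 12 held 10 µM forskolin, 10 µg/mL insulin, 200 µg/mL ascorbic acid-2 phosphate and 10 µM DAPT. The protocol names another gamma-secretase inhibitor as a substitute for DAPT, and the series' design text names DAPT. Groups and replicate numbers were taken from the labels. The labels do not say whether replicates are separate cultures.

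The deposited table of non-normalized values gives, for each of 47292 probes and each array, an intensity on a linear scale and a detection p-value, per the file headers. Per the submitters' processing notes the tool was BeadStudio, with no version given. Per the labels' protocols 250 ng of total RNA was labelled per array. A deposited value table holds a processed intensity for the same probes and arrays, and its method of normalization is not stated. Its values show that background was subtracted, that a floor of 20 was set and that each array was brought to the first hESC array along a curve depending on intensity. That table was used only as an alternative source. Each of its columns ranked the probes most like the array whose label it carries. No pair of arrays held identical values, and 0 columns lacked a sample.

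Probes were named through the platform annotation provided with the files. It gave 1 gene symbol to 30098 probes, several to 8 and none to 17186. Symbols were brought up to date through the gene identifier in a RefSeq gene table, which matched 30059 probes, and the annotation's own symbol was kept for the other 39. No gene was named from a probe with several symbols, and probes without a symbol entered no gene test. A probe entered if its detection p-value was under 0.05 on at least 4 of the 32 arrays, which 23659 probes met, 17240 of them with a symbol. A gene was represented by its probe with the highest mean over all arrays, which gave 13309 genes, 3234 of them with several such probes. This rule can pick a probe that also binds other transcripts, as it did not test what a probe binds. The array number limits the precision of every value. Detected probes per array numbered from 13440 to 18212, and mean intensity per array ran from 146.4 to 228.4.

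Background correction and normalization were done with neqc of limma 3.58.1 in R 4.3.3. It fits the background from the intensities and detection p-values, adds an offset of 16, takes log2 and brings all arrays to the same distribution by quantiles. Fold changes are therefore on the log2 scale of these values, and the offset makes changes of dim genes smaller than they are. Quantile normalization also removes any change in the total level of RNA, so each change is relative to the other genes. Group means were fitted to all 32 arrays with lmFit and eBayes of limma, and p-values were adjusted by the Benjamini-Hochberg method over all 13309 genes. A gene was called at an adjusted p under 0.05. The spread of a gene is pooled over all groups, so a gene uneven in hESC or endoderm, such as ALB, is tested less sensitively at day 12. Adjusted p-values given for genes are from this fit, standard errors (SE) are its residual errors of the log2 fold change, and values after ± are standard deviations (SD) of 4 arrays unless named SE. Where a gene was detected on no array of a group, its fold is a lower bound, written "at least". That bound sets the mean of the other group against the mean, over the arrays of the undetected group, of the lowest normalized level among detected probes or the gene's own level, whichever was higher. A fold against a group that detected the gene on only some of its arrays is taken from the measured level, which can lie near background, and is imprecise. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

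The comparisons were endoderm against hESC, liver bud against endoderm, base hepatic progenitors against liver bud and against hESC, each of the 4 withdrawals against base, and each of the 6 pairs of withdrawals. Shifts of gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. The 40 lists held 827 genes in all and were written from general knowledge, without the files. A list needed at least 5 measured members. Camera asks whether the genes of a list moved more than the other genes. The test was repeated with a correlation estimated for each list, and fry of limma asked whether the genes of a list moved on balance in 1 direction. The design, the alternatives, the lists and the rule for naming genes were fixed before the data were examined. That rule names, per comparison, the 6 genes with the highest and the 6 with the lowest log2 fold change among those called, changed at least 2-fold and without overlap between the 4 and 4 arrays. It adds up to 4 members with the largest change from each list described, and a fixed set of stage, liver and pathway genes. Symbols starting with LOC, HS. or FLJ were left out. Of the fixed genes, HNF4A, CYP3A4 and KRT7 are not analysed here.

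Alternatives were no background correction, median scaling in place of quantiles, the deposited processed values, no filter on dim probes, a filter asking for detection on all 4 arrays of either group, the mean of a gene's probes, trend and robust moderation, the replicate number as a block, only the 8 arrays compared, a 2-fold minimum and leaving out each array in turn. A fit with each array's log2 mean intensity as a covariate and a fit without the day 12 arrays under 15000 detected probes were chosen after seeing the data. Overlaps between withdrawals, which share the base arrays, were set beside the overlap of independent lists, 50 simulations of unchanged groups and the 6 ways of splitting the base arrays 2 and 2. The BeadChip was not used as a block because the files name no chip.

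The scripts' fits were tested on simulated data with the real genes' means and spread, with 200 of 13309 genes changed in each of the 8 comparisons. In the simulated comparisons without forskolin and without AAP, 16% and 20% of genes changed 1.2-fold were called, 88% and 82% of those changed 1.5-fold, and all of those changed 4-fold. In the simulated comparisons without DAPT and without insulin, 14% and 8% of genes changed 1.2-fold were called, and 86% in both at 1.5-fold. Across the 4 stage comparisons between 70% and 82% of genes changed 1.5-fold were called, and between 94% and 100% of those changed 2-fold. False calls numbered from 7 to 13 per comparison. A list shifted by 0.5 log2 was called in 8 of 8 comparisons, and 0 of the lists sharing no member with it were. The simulated genes varied independently of each other. This 0 therefore does not test false calls of lists whose genes vary together, as the plasma protein genes did (estimated correlation 0.26).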

Results

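Gene expression was measured on 32 arrays, 4 for each of 8 groups, along the differentiation of H1 human embryonic stem cells (hESC) through definitive endoderm at day 2 and liver bud progenitors at day 6 to hepatic progenitors at day 12. At day 12 there were 5 groups: the full base medium and the base medium without DAPT, without forskolin, without AAP or without insulin. DAPT blocks gamma-secretase and so Notch signalling, forskolin raises cyclic AMP, AAP (ascorbic acid-2 phosphate) is a stable form of vitamin C, and insulin acts through its receptor on metabolism and growth. Mean detected probes per array were 17108.5 ± 549 for hESC, 17284.5 ± 774 for endoderm, 16726.5 ± 1043 for liver bud and 15758.5 ± 1120 for base (SD, n = 4). They were 17066 ± 765 without DAPT, 15611 ± 1049 without forskolin, 14934 ± 1377 without AAP and 16949 ± 622 without insulin. The first principal component held 64.5% of the variance and ordered the stages from day 0 and day 2 over day 6 to day 12, and the second, with 12.7%, parted endoderm from hESC. The replicates are not stated to be separate cultures, so each p-value measures only the spread between these samples, which may be technical.

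**Figure D1:**
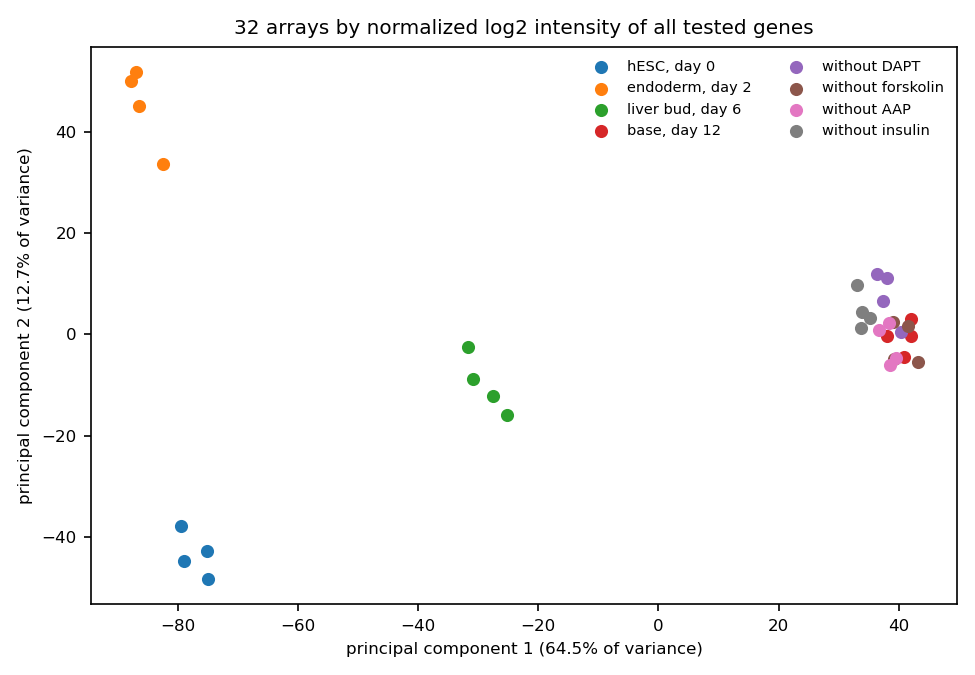
Each point is 1 of the 32 arrays at its scores on the first principal component (64.5% of variance) and the second (12.7%) of normalized log2 intensity over 13309 genes, coloured by group. The 20 day 12 arrays lie together on the right, away from the other stages.

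The step from hESC to day 2 asked which genes mark the formation of definitive endoderm. The cells switched on the signals and transcription factors of the primitive streak and endoderm and lost a part of the stem cell programme. LEFTY1 and LEFTY2, secreted inhibitors of Nodal that Nodal itself induces, rose 264-fold and 244-fold (n = 4 and 4). EOMES, the factor that opens the endoderm programme, went from undetected to a log2 level of 11.91 ± 0.34, at least 167-fold higher, and CER1, a secreted antagonist of Nodal, BMP and WNT, rose at least 68.2-fold. SOX2, a core factor of the stem cell state, fell by 5.49 (SE 0.17) on the log2 scale.

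At day 2, 16 of the 18 measured definitive endoderm genes were higher and none was lower (median log2 change 3.06, camera adjusted p = 2.5e-15). FOXA2, the pioneer factor of endoderm, rose by 6.14 (SE 0.11, adjusted p = 2.1e-28). SOX17, which fixes endoderm identity, rose at least 39.6-fold, the surface receptor CXCR4 at least 20.5-fold, and HHEX, needed later for the liver bud, by 3.70 (SE 0.18). PRDM1 rose 60.1-fold. Of 11 primitive streak genes, 10 were higher (median 2.40, or 2.17 with undetected genes at their bounds, adjusted p = 2.9e-12). They included the growth factors FGF17, at least 45.8-fold higher, and NODAL, 49.3-fold higher, and the organizer gene LHX1, at least 15.9-fold higher. Among 13 targets of Nodal and TGF-beta signalling 8 rose and 1 fell (median 1.98, adjusted p = 1.3e-05). CYP26A1, which degrades retinoic acid, rose 75.3-fold from a detected level, and the scavenger receptor COLEC12 rose 75.6-fold.

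The stem cell genes did not fall as a block. Of 17 pluripotency genes 10 fell, 2 rose and 5 did not pass the test (median -0.65, with bounds -0.46, camera adjusted p = 0.00041). FGF2, a growth factor that keeps hESC undifferentiated, fell by 3.89 (SE 0.11), the cell surface marker THY1 by 2.86 (SE 0.07), and the deubiquitinase USP44 at least 8.57-fold. NANOG, which endoderm keeps longer than other stem cell factors, fell by 0.83 (SE 0.08, adjusted p = 6.6e-10), from 6.85 ± 0.13 to 6.02 ± 0.21. The probe that stood for POU5F1 was near background in both groups (4.48 and 4.46) and gave no measure of this gene, and with the mean of its probes POU5F1 fell by 0.23, and with a stricter filter on detection by 0.48. The metallothionein MT1G fell at least 86.7-fold, and NPTX1, a pentraxin of synapses, LDB2, a cofactor of LIM domain proteins, and CAMKV fell by between 4.97 and 5.22 on the log2 scale. VSNL1, a calcium sensor, fell at least 27.4-fold to below detection.

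Chaperones of the endoplasmic reticulum rose in 16 of 18 cases (median 1.19, adjusted p = 2.6e-07), led by MANF, which rose 5.07-fold, CRELD2 with 4.18-fold and DNAJB9 with 3.21-fold. Targets of the hypoxia factor HIF fell in 20 of 28 cases and rose in 2 (median -0.92, adjusted p = 2.6e-07). FAM162A dropped by 3.47 (SE 0.16) and the glucose transporter SLC2A1 by 3.32 (SE 0.13). In all, 6791 of 13309 genes changed, 3354 up and 3437 down, 1771 of them at least 2-fold. The hESC arrays also carried liver transcripts: on hESC replicate 3, 33 genes that were bright at day 12 and near background at day 2 had a median of 2.28% of their day 12 signal. The medians on hESC replicates 1, 2 and 4 were 0.748%, 0.220% and 0.877%. Of the 33 genes, 24 were called lower at day 2 and 1 higher, and the 24 made up 0.698% of the genes called lower.

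The step to the liver bud at day 6 asked which genes follow the patterning of endoderm by BMP4, activin and cyclic AMP. The protocol also lists a WNT inhibitor on days 4 and 5 with a plus/minus sign, and which samples received it is not given, so that the part of WNT in the day 6 values is open. Genes of secreted liver proteins came on and the endoderm and streak signals went off. TTR, which carries thyroid hormone and retinol, rose 249-fold from 4.67 ± 0.58 to 12.63 ± 0.19 (n = 4 and 4, adjusted p = 2.5e-20). The fibrinogen chains FGB, FGG and FGA rose 220-fold, 188-fold and 138-fold over day 2 levels near background, where 1, 1 and 2 of 4 arrays detected them. AFP, the albumin of the fetal liver, rose 145-fold (SE 0.59 on the log2 scale) with an uneven start of 6.67 ± 2.37 at day 2, and 288-fold without endoderm replicate 1 and 82.5-fold without endoderm replicate 4. LEFTY1 fell by 7.76 (SE 0.24), and SOX17 and CXCR4 fell below detection, at least 39.2-fold and 20.3-fold.

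Transcription factors of the liver bud rose in 14 of 17 cases and fell in 3 (median 1.62, with bounds 1.61, camera adjusted p = 8.9e-07). NR5A2, which governs bile acid and cholesterol genes, rose at least 21.7-fold, CREB3L3 at least 11.5-fold, FOXA1 12.5-fold and ONECUT2 13.4-fold. PROX1, TBX3 and CEBPA, which direct bud outgrowth and hepatocyte fate, rose at least 8.84-fold, 9.28-fold and 11.4-fold. Of 21 plasma protein genes 12 rose and none fell (median 1.27, with bounds 1.00, adjusted p = 1.3e-05; adjusted p = 0.072 with an estimated correlation). ALB reached 10.17 ± 0.31 from 5.21 ± 0.54, SERPINA1, the inhibitor of elastase, rose 140-fold and the iron carrier TF 56.3-fold. APOA1, the main protein of HDL, rose 37.4-fold. Coagulation and complement genes rose in 15 of 31 cases with none lower (median 0.37, with bounds 0.18, adjusted p = 1.1e-05), among them C5, up by 3.80 (SE 0.10) on the log2 scale.

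The day 2 programme receded. Of 11 primitive streak genes 10 fell (median -2.41, with bounds -2.16, adjusted p = 2e-11), and of 18 definitive endoderm genes 11 fell and 6 rose (median -1.79, adjusted p = 0.00059). EOMES fell by 6.69, CER1 by 6.04, SHISA2 by 4.79 and NODAL by 2.62 on the log2 scale. CYP26A1 fell by 6.89 (SE 0.33), ZIC2, a factor of the early embryo, by 6.09, and the proteoglycan GPC4 by 6.27. NANOG fell at least 2.80-fold to below detection. SOX2 went the other way and rose by 3.46 (SE 0.17), from 5.18 ± 0.15 to 8.64 ± 0.24, below its hESC level of 10.66 ± 0.19. Targets of BMP rose in 9 of 13 cases and fell in 2 (mean 1.59, median with bounds 0.93, adjusted p = 0.00053). ID1 and ID2, immediate BMP targets that hold back differentiation, rose 49.4-fold and 48.9-fold, and the BMP decoy receptor BAMBI 11.8-fold. DKK1, a secreted WNT antagonist, rose 17.5-fold to 11.06 ± 0.23.

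Cholesterol synthesis genes fell in 16 of 20 cases and rose in 3 (median -1.13, adjusted p = 3.9e-05), with ACAT2, INSIG1 and IDI1 down by 2.59, 2.48 and 1.86 on the log2 scale. Targets of ATF4, the factor of the amino acid response, fell in 19 of 25 cases (median -0.72, adjusted p = 8.9e-07), with the amino acid transporter subunits SLC7A5 and SLC3A2 down by 3.44 and 2.54. PDX1, the factor of pancreas and duodenum, rose 17.3-fold to 8.52 ± 0.14, and SPINK1, a trypsin inhibitor of pancreas, gut and fetal liver, rose 84.0-fold. The 6 measured pancreas genes were not called as a list by camera: 2 rose and 2 fell, the median change was -0.06 (with bounds 0.00) and the mean 1.53 (camera adjusted p = 0.22). Under 1 alternative setting the list was called. In total 6776 genes changed, 3432 up and 3344 down, 1747 at least 2-fold. Under median scaling 34.9% of calls were higher, against 50.6% here.

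**Figure D2:**
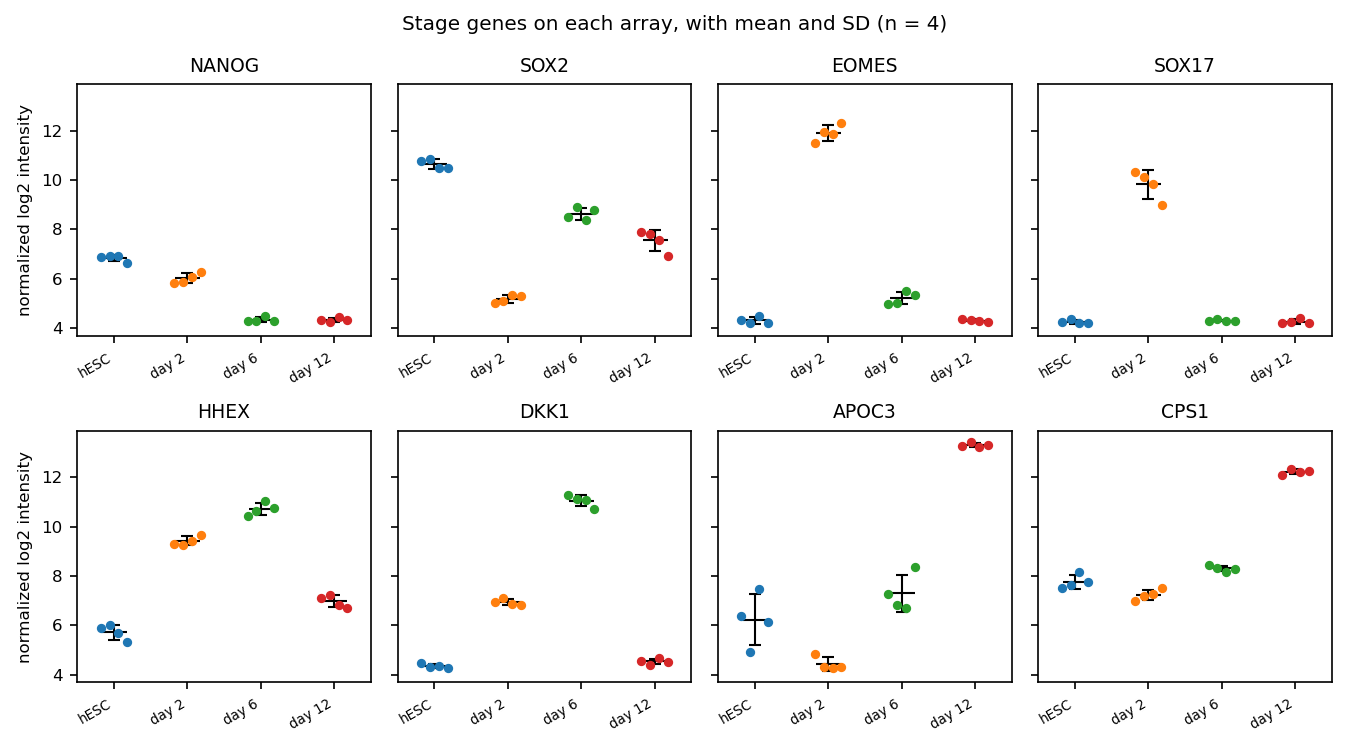
Normalized log2 intensity of 8 genes on the arrays of hESC, day 2, day 6 and day 12 (base), 4 per stage, with points for arrays and bars for the mean and SD. EOMES and SOX17 peak at day 2, HHEX and DKK1 at day 6, and APOC3 and CPS1 at day 12, while SOX2 falls at day 2 and is higher again at day 6.

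The step from liver bud to base hepatic progenitors at day 12 asked which liver functions follow the 6 days in the full medium. Genes of lipid transport, the urea cycle and clotting rose, and cell cycle genes fell. APOC3, which slows the breakdown of plasma triglycerides, rose 64.5-fold to 13.31 ± 0.07, and APOA4, made by gut and fetal liver, 57.1-fold (n = 4 and 4). CPS1, the entry enzyme of the urea cycle, rose 15.1-fold to 12.22 ± 0.10 (adjusted p = 1.2e-23). ALB rose 9.91-fold to 13.48 ± 0.14. DKK1 fell by 6.52 (SE 0.20), back to a level of 4.53 ± 0.11.

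Clotting and complement genes rose in 24 of 31 cases with none lower (median 1.11, with bounds 1.05, camera adjusted p = 8e-13). SERPINC1, which makes antithrombin, rose 30.8-fold, the kininogen gene KNG1 28.7-fold, plasminogen PLG 17.8-fold and complement CFB 15.9-fold. Apolipoprotein genes rose in 14 of 18 cases (median 1.13, with bounds 1.04, adjusted p = 2.4e-07), with APOC2 14.4-fold and APOC1 5.41-fold higher. Of 24 genes of the urea cycle and amino acid breakdown 16 rose and 3 fell (median 1.42, with bounds 1.24, adjusted p = 2.4e-07). AGXT, which detoxifies glyoxylate, rose 46.8-fold, HGD 21.5-fold and ASS1, which joins citrulline and aspartate, 17.6-fold. TAT, a late marker of hepatocytes induced by glucocorticoids, rose at least 4.52-fold from below detection. CYP3A7, the main cytochrome of the fetal liver, rose 7.56-fold. AFP was the brightest probe on every day 12 array, 20 of 20, so that quantile normalization gave it the same level of 14.44 on all of them and no difference between day 12 groups could be measured. Its mean intensity before normalization was 22499 ± 2521 in base and 24442 without DAPT, the highest group.

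Genes of gluconeogenesis, cholesterol synthesis and the response to hypoxia rose. Gluconeogenesis genes rose in 10 of 13 cases and fell in 1 (median 1.62, adjusted p = 1.8e-06), with the coactivator PPARGC1A up 7.07-fold and FBP1 5.11-fold. Of the rate-setting enzymes, PCK1 rose by 0.55 (SE 0.14) and G6PC1 by 0.46 (SE 0.15, adjusted p = 0.013), both close to background. Neither was called under median scaling (adjusted p = 0.099 and 0.094) or with the series matrix values (change 0, adjusted p = 1.0 for both), and G6PC1 was not called with brightness as a covariate (adjusted p = 0.12) or without base replicate 1 (0.086). Cholesterol synthesis genes, low at day 6, rose in 16 of 20 cases (median 1.78, adjusted p = 4.3e-09), INSIG1 by 9.37-fold and MSMO1 by 5.79-fold. HIF targets rose in 21 of 28 cases and fell in 2 (median 1.00, adjusted p = 4.1e-09). LOX, the enzyme that crosslinks collagen, rose 34.9-fold, ALDOC 19.6-fold and NDRG1 18.3-fold.

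Cell cycle genes fell in 24 of 27 cases with none higher (median -2.16, adjusted p = 8.5e-14). CDC20 fell by 3.13 (SE 0.18), CCNB2 by 3.01 and TOP2A by 2.97 on the log2 scale, and outside the list the centromere protein CENPF fell by 3.41. The liver bud factors parted: 5 of 17 rose, 9 fell, and the list as a whole was not called (median -0.48, adjusted p = 0.35). ATF5 rose 17.3-fold and CREB3L3 9.04-fold, while HHEX fell by 3.75 and ONECUT2 by 3.32. HES1, a Notch target, fell by 1.75 (SE 0.13) over the step that added DAPT. A part of this fall did not need DAPT, since HES1 read 5.48 to 5.87 at day 12 without it, against 6.77 to 6.92 at day 6. NPY, FST, ALPL and SOX2 fell by 4.36, 3.89, 3.83 and 1.09. Genes of the intestine rose too. Of 8 mid and hindgut genes 5 rose and none fell (median 0.45, with bounds 0.33, adjusted p = 0.0044), among them the cadherin CDH17, 21.6-fold up, its regulator CDX2, 4.21-fold up, and TFF3. MEP1A, a protease of the brush border, and ZG16, a secreted lectin, rose 50.9-fold and 86.9-fold, and SI, sucrase-isomaltase, chosen after its values were seen, rose by 3.24 (SE 0.09). VIL1, a villus protein of that list, rose by 0.64, but changed by -0.037 under median scaling. In total 6734 genes changed, 3142 up and 3592 down, 1832 at least 2-fold. Median scaling moved the median gene by -0.26 and made 17.9% of the calls higher, against 46.7%.

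Base hepatic progenitors against hESC gave the whole distance travelled. Genes of secreted liver proteins were among those that rose most, and stem cell and cell cycle genes were lower. APOC3 was 135-fold higher, APOA2, of HDL, 104-fold, FGG 99.4-fold, TF 97.7-fold and APOB, the scaffold of LDL, 97.6-fold (n = 4 and 4). These folds rest on hESC levels that varied between arrays, such as 6.23 ± 1.04 for APOC3 and 7.57 ± 1.10 for ALB. Where the liver transcripts on the hESC arrays do not come from hESC, such folds are too low. ZIC2 was lower by 6.12 (SE 0.18) and the RNA-binding protein L1TD1 by 5.61 (SE 0.21) in hepatic cells, both falling from high hESC levels of 11.08 ± 0.24 and 11.61 ± 0.19.

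All 17 measured liver bud factors were higher than in hESC (median 2.00, camera adjusted p = 2.4e-10), with CREB3L3 86.6-fold, FOXA2 65.3-fold, FOXA1 47.5-fold and ATF5 32.6-fold up. Of 21 plasma proteins 19 were higher (median 3.66, with bounds 3.50, adjusted p = 1.9e-10), among them TTR with 89.6-fold, SERPINA1 with 85.2-fold and AHSG, fetuin A, with 67.5-fold. Genes for foreign compounds and bile acids were higher in 21 of 28 cases and lower in 1 (median 1.34, with bounds 1.16, adjusted p = 1.5e-08). The glutathione transferases GSTA1 and GSTA2 rose 78.6-fold and 64.8-fold, the bile acid importer SLC10A1 54.8-fold and the sulfotransferase SULT2A1 17.5-fold. CYP3A7 rose at least 7.61-fold, CPS1 22.1-fold, and the membrane protein TM4SF4 93.6-fold.

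Of 17 pluripotency genes 16 were lower (median -2.81, adjusted p = 1.9e-10). THY1 fell at least 27.0-fold, NANOG at least 4.84-fold, the DNA methyltransferase DNMT3B by 4.80 and PODXL by 4.62 on the log2 scale. SOX2 fell by 3.11 (SE 0.17) and was still detected on 4 of 4 base arrays. ZSCAN10 fell by 5.51, the WNT modulator SFRP2 at least 39.5-fold and the noncoding RNA SNAR-A1 by 5.13. Cell cycle genes were lower in 26 of 27 cases (median -2.90, adjusted p = 5.9e-14), where BUB1 fell by 4.31, TOP2A fell by 4.29 and UBE2C fell by 3.93. Mid and hindgut genes were higher in 5 of 8 cases (median 1.71, with bounds 1.48, adjusted p = 0.0026), with CDX2 at least 8.58-fold and VIL1 at least 7.54-fold up. In all 7918 genes changed, 3843 up and 4075 down, 3022 at least 2-fold. Median scaling moved the median gene by -0.29, with 22.0% of calls higher, against 48.5%.

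**Figure D3:**
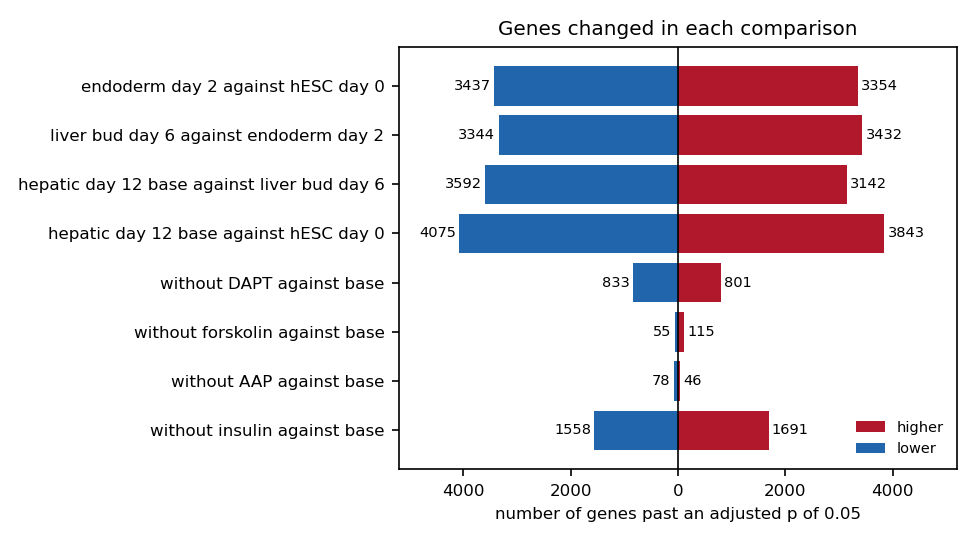
Number of genes called higher (right) and lower (left) at an adjusted p of 0.05 in each of 8 comparisons of 4 and 4 arrays, over 13309 genes. Counts run from 124 without AAP to 7918 for base against hESC.

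Leaving out DAPT asked what Notch inhibition does in the last 6 days. Without it glycolysis, collagen and hypoxia genes were higher as lists and those of the amino acid response lower. Outside glycolysis most members of these lists did not pass the test, and the arrays of this group were brighter than base. EPO, the hormone of red cell growth that fetal liver makes and hypoxia induces, rose 3.09-fold, from 4.74 ± 0.19 to 6.37 ± 0.27 (n = 4 and 4, adjusted p = 7.3e-10). The intestinal cadherin CDH17 fell by 1.75 (SE 0.16, adjusted p = 1.5e-08). HAMP, hepcidin, the iron hormone, fell by 1.25 (SE 0.21). HES1, the standard target of Notch, rose by 0.52 (SE 0.13, adjusted p = 0.0069). Compared directly, its level did not pass the test against AAP withdrawal (0.13, adjusted p = 0.53) or forskolin withdrawal (0.33, adjusted p = 0.060). Against insulin withdrawal it did (0.40, adjusted p = 0.014).

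The Notch target list as a whole did not move: 3 of 16 rose, 1 fell and 12 did not pass (median 0.04, with bounds 0.00, camera adjusted p = 0.55). Genes of bile duct epithelium, the fate Notch favours in liver, rose in 2 of 18 cases with none lower (median -0.02, with bounds 0.00, mean 0.06, adjusted p = 0.71). KRT19, a keratin of bile ducts, rose by 0.74 (SE 0.21, adjusted p = 0.022), but was not called without base replicate 1 (adjusted p = 0.055) or 2 (0.096), or without replicate 1 (0.082) or 2 (0.062) of the group without DAPT. SOX9 changed by 0.23 (SE 0.15, adjusted p = 0.33). Glycolysis genes rose in 12 of 18 cases with none lower (median 0.67, adjusted p = 1.8e-09), including PFKP, 1.83-fold up, and ENO2, 1.67-fold up. With array brightness as a covariate the median was 0.35 and 6 of the 18 were called. HIF targets rose in 9 of 28 cases (median 0.20, adjusted p = 6.3e-07), with LOX and PFKFB4 up 1.57-fold and 1.55-fold. Adjusted over the list alone, 13 HIF targets rose and 1 fell.

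Collagen genes rose in 8 of 28 cases, or 12 adjusted over the list alone (median 0.29, adjusted p = 9.8e-06), led by COL11A1, 2.06-fold up, COL5A2, 2.00-fold up, and PCOLCE. Targets of ATF4 fell in 9 of 25 cases with none higher (median -0.04, mean -0.20, adjusted p = 0.0022). The amino acid importer SLC7A1 fell by 1.12, MTHFD2, of the mitochondrial folate cycle, by 1.24, and asparagine synthetase ASNS by 0.74 (SE 0.11). The glycine transporter SLC6A9, outside the list, fell by 1.21. Cell cycle genes rose in 9 of 27 cases and fell in 1 (median 0.18, adjusted p = 0.00046; adjusted p = 0.14 with an estimated correlation), with TOP2A and UBE2C up 2.23-fold and 2.09-fold, and ASPM, a spindle protein outside the list, rose 2.28-fold. Plasma protein genes rose in 9 of 21 cases (median 0.30, adjusted p = 1.7e-05; adjusted p = 0.18 with an estimated correlation), with AGT and LBP up 1.96-fold and 1.72-fold. CYP3A7 rose 1.92-fold, the steroid transporter SLC51A 2.12-fold, HLA-B 2.30-fold and LEFTY1 2.22-fold, the last to a level of 5.62 ± 0.75. ALB did not pass the test (-0.18, SE 0.30, adjusted p = 0.75).

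The intestinal genes moved apart without DAPT. While CDH17 fell, and SI, chosen after its values were seen, fell by 1.15 (SE 0.09), the regulator CDX2 changed by 0.12 (adjusted p = 0.53) and ANXA13, of the same list, rose from below detection to 5.17 ± 0.14, a call lost with the series matrix values (adjusted p = 0.21). Of 8 genes 2 rose and 1 fell, and the list was not called (median 0.04, mean -0.11, adjusted p = 0.83). In total 1634 genes changed, 801 up and 833 down, 27 of them at least 2-fold. The count was 814 without base replicate 2, and 982 and 892 without replicates 1 and 2 of the group without DAPT. The 2-fold count was 18 without base replicate 2 and 55 without replicate 4 of the group without DAPT. It was 2 with no background correction, 79 with the series matrix values and 152 under median scaling. The arrays without DAPT were brighter than base, with a mean intensity of 184 ± 7.64 against 163 ± 8.08, and with brightness as a covariate 721 genes were called, 517 of them among the 1634 in the same direction, and with the series matrix values 1024. Median scaling moved the median gene by 0.21, and 97.9% of its 3120 calls were higher.

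Leaving out forskolin asked what raised cyclic AMP adds. Few genes moved. DKK1, the WNT antagonist that base cells had silenced, was 4.57-fold higher, at 6.73 ± 0.76 against 4.53 ± 0.11 (n = 4 and 4, adjusted p = 2.5e-08). TKTL1, a relative of the pentose phosphate enzyme transketolase, rose by 1.85 (SE 0.10), and FMO1, the flavin monooxygenase of fetal liver, 2.05-fold. ASS1 fell by 1.30 (SE 0.19, adjusted p = 0.00011), and HSD3B1, of steroid synthesis, by 1.35 (SE 0.13).

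None of 20 measured targets of CREB, the factor that cyclic AMP activates, passed the test in limma (median -0.06, with bounds -0.03, camera adjusted p = 0.34), while 1459 of all genes had an unadjusted p under 0.05. This depended on the fit for some targets. RGS2 was called under 2 other settings (lowest limma adjusted p = 0.0039) and DUSP1 under 1 (0.010). SIK1 was called under 1 other setting and with 1 array left out (lowest 0.016). CREM and NR4A1 were near background in both groups, and PPARGC1A and PCK1 changed by 0.21 and -0.33 with adjusted p-values of 0.60 and 0.38. Genes of the urea cycle and amino acid breakdown went both ways, 4 of 24 up and 2 down (median 0.03, with bounds 0.01, mean -0.02, adjusted p = 1.0). DPYS rose 1.54-fold and TAT fell by 0.52 (SE 0.10, adjusted p = 0.0031; 0.11 under median scaling and 0.16 in a fit of the 8 arrays alone). Glucocorticoid and metallothionein genes were lower as a list (median -0.21, adjusted p = 0.00085), with 2 of 16 called over all genes and 5 adjusted over the list alone. That list was not called without replicate 1 of the group without forskolin (adjusted p = 0.054). Targets of FOXO, which insulin represses, were slightly lower as a list (median -0.16, with bounds -0.13, adjusted p = 0.00085), though none of 21 was called. Genes for foreign compounds and bile acids rose in 3 of 28 cases, among them ADH1A, 1.90-fold up, and the list was not called (median 0.08, with bounds 0.04, adjusted p = 0.062; 0.024 without base replicate 3 and 0.029 without base replicate 4). ALB changed by 0.07 (SE 0.30). LCE6A, ZG16, IQCF6 and TPBGL fell by 1.32, 1.29, 1.24 and 1.17, where ZG16 was not called with the series matrix values (adjusted p = 0.073). In total 170 genes changed, 67.6% of them up and 55 down, 12 at least 2-fold. The count was 105 without replicate 3 of the group without forskolin, 111 with the series matrix values, 44 in a fit of the 8 arrays alone and 503 with brightness as a covariate. Under median scaling 90.9% of calls were higher, and without base replicate 4 57.6% were.

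Leaving out AAP asked what vitamin C adds. With all arrays it gave the lowest count of called genes. CIDEC, a coat protein of lipid droplets, fell by 1.10 (SE 0.10, adjusted p = 2.9e-08), from 8.27 ± 0.16 to 7.17 ± 0.13 (n = 4 and 4). In this fit CIDEC was the only gene called with a change of at least 2-fold. With the series matrix values 11 genes were, and with no background correction 0. PFKFB4, a regulator of glycolysis and a HIF target, fell by 0.55 (SE 0.10, adjusted p = 0.0027). The complement gene C8A fell by 0.48 (SE 0.09, adjusted p = 0.0037). In a fit of the 8 arrays alone neither was called (adjusted p = 0.11 and 0.21). Other liver genes, chosen after their values were seen, changed more. CYP8B1 fell by 0.95 (SE 0.09, adjusted p = 8.0e-08) and ARG1 by 0.82 (SE 0.12, adjusted p = 0.00020). APOH fell by 0.96 (SE 0.13, adjusted p = 4.5e-05), to a level detected on 2 of 4 arrays. SERPINA7 rose by 0.82 (SE 0.08, adjusted p = 8.0e-08). ALB (-0.39, SE 0.30) and CPS1 (0.03, SE 0.11) did not pass the test. The SE of ALB pools the spread of all groups, the uneven hESC and endoderm arrays included. On the arrays compared, ALB read 13.09 ± 0.10 without AAP and 13.48 ± 0.14 in base, without overlap, so a lower level is not excluded.

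Collagens, whose hydroxylation needs vitamin C, were not called as a list by camera: 1 of 28 rose, 1 fell and 26 did not pass (median -0.10, camera adjusted p = 0.052). The list was called without base replicate 2 (0.041), without replicate 4 of the group without AAP (0.049) and under 7 alternative settings. COL1A1 fell by 0.39 (SE 0.08, adjusted p = 0.012), but not without replicate 4 of the group without AAP (adjusted p = 0.057). Metallothionein and glucocorticoid genes rose as a list (median 0.20, adjusted p = 4e-05), with 4 of 16 called. Its 4 largest changes were those of the metallothioneins MT1E, MT2A, MT1F and MT1G (0.88, 0.54, 0.54 and 0.41). The glucocorticoid targets DUSP1 and TAT changed by -0.36 and 0.10 and did not pass the test (limma adjusted p = 0.23 and 0.82). MT1E rose 1.84-fold (adjusted p = 0.013), but was not called without base replicate 1 (0.051) or 2 (0.053) or replicate 3 of the group without AAP (0.071). HIF targets were lower as a list (median -0.16, adjusted p = 9.7e-05; adjusted p = 0.056 with an estimated correlation), with 1 of 28 called; VEGFA changed by -0.37 (adjusted p = 0.31). Cell cycle genes were higher as a list (median 0.11, adjusted p = 1.4e-05; adjusted p = 0.056 with an estimated correlation), with 3 of 27 called. Clotting and complement genes were lower as a list (median -0.10, adjusted p = 0.0078; adjusted p = 0.19 with an estimated correlation), with 2 of 31 called. Without base replicate 4 that list was not called (adjusted p = 0.080). In total 124 genes changed, 46 up and 78 down. The count was 74 without base replicate 3, 81 without base replicate 4, and 68 and 82 without replicates 2 and 3 of the group without AAP. It was 47 under median scaling, 79 with the series matrix values, 20 in a fit of the 8 arrays alone and 313 with brightness as a covariate. Median scaling made 53.2% of calls higher, against 37.1%, and without replicate 3 of the group without AAP 26.8% were.

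Leaving out insulin asked which genes depend on it in the last 6 days. Genes that insulin holds down came on and genes of lipid synthesis and HIF targets fell. IGFBP1, which binds insulin-like growth factors and is repressed by insulin in liver, rose 37.3-fold, from 4.66 ± 0.06 to 9.88 ± 0.32 (n = 4 and 4, adjusted p = 1.9e-24). PDK4, which shuts off pyruvate oxidation in fasting, rose 17.1-fold, and G6PC1, the last step of glucose output, 4.89-fold. SCD, the desaturase of fatty acids, fell by 1.02 (SE 0.07) and CIDEC by 2.43 (SE 0.10).

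Targets of FOXO rose in 13 of 21 cases and fell in 3 (median 0.53, camera adjusted p = 1.8e-07). FBXO32, of muscle wasting, rose 3.61-fold and IRS2, the insulin receptor substrate under FOXO control, 2.49-fold. DEPP1, which FOXO also induces, rose 8.48-fold. Gluconeogenesis genes rose in 7 of 13 cases with none lower (median 0.29, adjusted p = 8.4e-05), with PPARGC1A up 3.17-fold, FBP1 1.61-fold and PCK1 1.52-fold. The glucose transporter SLC2A2 rose 7.33-fold. Fatty acid synthesis genes fell in 12 of 19 cases and rose in 1 (median -0.60, adjusted p = 8.6e-08), with ACSS2, MLXIPL and FASN down by 1.44, 1.05 and 0.79. SREBF1, the factor through which insulin drives them, fell by 1.17 (SE 0.13). Cholesterol synthesis genes fell in 12 of 20 cases (median -0.56, adjusted p = 8.4e-07), with CYP51A1, INSIG1, FDPS and HMGCS1 down by 1.19, 1.19, 1.19 and 1.10.

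HIF targets fell in 16 of 28 cases and rose in 1 (median -0.43, adjusted p = 8.8e-09), with ALDOC down by 2.21, PFKFB4 by 1.80, LOX by 1.71 and VEGFA by 0.68. Glycolysis genes fell in 10 of 18 cases (median -0.45, adjusted p = 0.00012; adjusted p = 0.10 with an estimated correlation), among them ALDOA by 1.38 (SE 0.23). Cell cycle genes fell in 13 of 27 cases and rose in 1 (median -0.31, adjusted p = 0.00016; adjusted p = 0.077 with an estimated correlation), with HMMR, CDC20 and UBE2C down by 0.97, 0.96 and 0.88. BMP targets rose in 7 of 13 cases and fell in 1 (median 0.24, with bounds 0.22, adjusted p = 8.4e-05). ID3 and ID1 rose 5.38-fold and 4.23-fold, HAMP, which BMP induces in hepatocytes, 2.62-fold, and SMAD6 2.18-fold. Bile duct genes rose in 7 of 18 cases (median 0.13, adjusted p = 0.027), with SOX4, CFTR and CD24 up 2.52-fold, 2.34-fold and 2.08-fold, and the list was not called under median scaling (adjusted p = 0.19) or with the mean of probes (0.051).

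Liver markers went both ways without insulin. CYP3A7 rose 3.61-fold and TAT by 0.58 (SE 0.10), ALB fell by 0.98 (SE 0.30, adjusted p = 0.013), and CPS1 changed by 0.07 (adjusted p = 0.69). TBX3, HHEX, FST and DKK1, each of which fell from day 6 to base, were 2.53-fold, 2.19-fold, 6.42-fold and 4.46-fold higher than in base. GPX3 rose 5.70-fold, and SLC51A, PPP1R3C, which targets glycogen, BHLHE40, MS4A10 and INSYN2A fell by between 2.45 and 2.66. In total 3249 genes changed, 1691 up and 1558 down, 367 at least 2-fold. The 4 arrays without insulin were each brighter than each base array (log2 mean intensity 7.42 to 7.62 against 7.24 to 7.41), and with brightness as a covariate 3675 genes were called, with 79.8% of the 3249 among them in the same direction. Median scaling moved the median gene by 0.11, with 81.8% of calls higher, against 52.0%. Of the 4 withdrawals it gave the highest count, except under median scaling (2821 genes, against 3120 without DAPT).

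**Figure D4:**
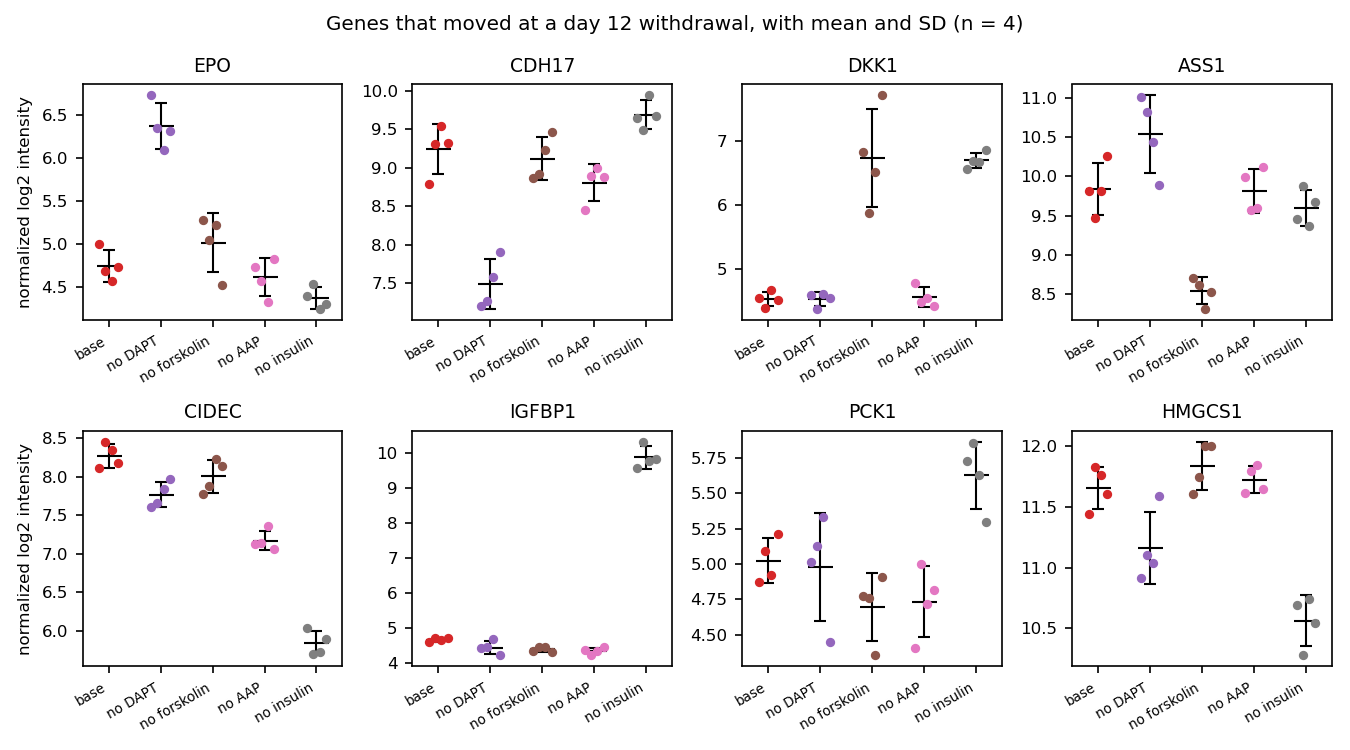
Normalized log2 intensity of 8 genes on the day 12 arrays of base and the 4 withdrawals, 4 arrays per group, with points for arrays and bars for the mean and SD. EPO lies at 6.37 and CDH17 at 7.49 without DAPT, against 4.74 and 9.24 in base, DKK1 is high without forskolin and without insulin, and IGFBP1 lies at 9.88 without insulin against 4.66 in base.

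Compared directly, so that the base arrays cancel, the withdrawals differed from each other in many genes. Insulin against DAPT withdrawal differed in 3845 genes, 481 of them at least 2-fold, against forskolin in 3162 (357) and against AAP in 3206 (335). DAPT withdrawal differed from that of forskolin in 2455 genes and from that of AAP in 2492 (1612 and 1566 with the series matrix values), while forskolin and AAP differed in 404. TKTL1 was higher without forskolin than without insulin by 2.11 (SE 0.10), and IGFBP1 was lower by 5.49. DKK1 did not differ between forskolin and insulin withdrawal (0.04, SE 0.20, adjusted p = 0.93), and was lower without AAP than without insulin by 2.13.

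Genes called in the same direction in a pair of withdrawals were most numerous for DAPT with insulin, 416, where independent lists would share 199, with 298 called in opposite directions. The pair of forskolin and insulin shared 87 (independent 21.1, opposite 26), among them DKK1, and that of AAP and insulin 74 (15.0, opposite 27), among them CIDEC. DAPT shared 38 with forskolin (10.4) and 40 with AAP (7.65), and forskolin shared 11 with AAP (0.720). Unchanged groups, simulated against a shared base group that was redrawn each time, shared 0 in 50 simulations. Unchanged groups leave few called genes to share, so this 0 cannot show how far a shared base raises an overlap. With the base arrays split so that the pair had no control in common, the mean shared number was 127 for DAPT with insulin, 30.8 for forskolin with insulin, 30.8 for AAP with insulin, 12.0 and 15.3 for DAPT with forskolin and AAP, and 3.00 for forskolin with AAP. The independent expectations were 73.8, 7.75, 6.55, 2.48, 2.09 and 0.210 in these smaller sets. The arrays without DAPT and those without insulin were both brighter than base (mean intensity 184 and 182 against 163). Splitting the base arrays does not remove this, and the part of brightness in the overlap of DAPT with insulin was not tested. Covariances of the fold changes, across genes, which are not independent replicates, were 0.0139, 0.0144 and 0.0144 for DAPT, forskolin and AAP with insulin, above the 0.00831 of the simulated groups. For DAPT with forskolin, DAPT with AAP and forskolin with AAP they were 0.00422, 0.00339 and 0.00846. Split controls gave 0.00622, 0.00669 and 0.00669 for the pairs with insulin, and -0.00344, -0.00428 and 0.000799 for the others.

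Of the camera calls reported above, 8 were lost with an estimated correlation, each with that value beside it, and the other reported calls held. Calls not reported above were lost too. Among them were coagulation and complement without DAPT (adjusted p = 0.013, and 0.18 with an estimated correlation) and acute phase targets without forskolin (0.045 and 0.56).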

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

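The tests of the glycolysis list, of the genes changed at least 2-fold, of the intestinal genes and of the liver transcripts on hESC arrays were chosen only after the results were seen, as was the fit with array brightness as a covariate. A value stood apart when its gap to the nearest of the other 3 arrays, divided by the range of its group, passed 0.829. This met 36 of 616 sets of a named gene and a group, or 5.84%, and chance alone gives about 1 in 20. Among the measures of whole arrays it met 1 of 16: replicate 4 without DAPT had 15923 detected probes (gap ratio 0.911), and the others had up to 17538.

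Endoderm replicate 1 stood apart for 3 genes of secreted liver proteins, FGB (0.942), FGG (0.870) and TTR (0.856). FGB read 5.31 there and up to 4.44 on the others. Endoderm replicate 4 stood apart for AXIN2 (0.883), MNX1 (0.849), OTX2 (0.854), THY1 (0.904) and ZIC2 (0.883), and replicate 2 for PROX1 (0.881). Liver bud replicate 4 was higher for ACSL5 (0.854), ALB (0.856), HGD (0.836) and ZG16 (0.858), genes that rise by day 12. Liver bud replicate 1 was higher for PDX1 (0.881) and VIL1 (0.843), and replicate 3 for NANOG (0.916) and PCK1 (0.861). Among hESC, replicate 3 stood apart for PODXL (0.904) and replicate 4 for VSNL1 (0.914).

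Base replicate 1 stood apart for APOB (0.876), FBP1 (0.914), NR4A1 (0.867), OTC (0.927) and SCD (0.890), replicate 2 for BHLHE40 (0.947), FST (0.840) and HLA-B (0.837), replicate 3 for TKTL1 (0.927), and replicate 4 for ATF5 (0.935), IRS2 (0.925) and MT2A (0.855). The others were SLC7A1 on replicate 4 without DAPT (0.864), TKTL1 on replicate 1 without forskolin (0.879), SERPINC1 on replicate 1 without AAP (0.860), and DEPP1 (0.888) and PFKFB4 (0.848) on replicates 3 and 2 without insulin. Of 17186 probes without a gene symbol, which no comparison used, 81 were detected on all 4 base arrays and on no hESC array, and 176 the other way. Named probes gave 393 and 747.

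Many genes moved by a small amount without DAPT while the arrays of that group were brighter, by 0.173 on the log2 scale, with each of its 4 arrays above each base array (7.46 to 7.58 against 7.24 to 7.41). Of the 1634 called genes 85.7% moved in the direction that the slope on brightness within groups gives, and the changes it gives correlated with those measured (Pearson r = 0.772 across genes, which are not independent), with a slope of 1.99 that the choice of called genes inflates. With brightness as a covariate, 22 of the 27 genes changed at least 2-fold were still called in the same direction. For glycolysis the median stayed at 0.35 of 0.67 with the list still called (camera adjusted p = 8.5e-09), though 6 of its members were called in place of 12. A linear effect of brightness, as estimated within groups, thus leaves a part of these changes. The 27 genes were chosen for large changes on these same arrays, and the 2 groups do not overlap in brightness. Brightness as the whole account is therefore not excluded. Of all 1634 genes 517 were still called in the same direction with the covariate, and for the others an effect of brightness and an effect of DAPT cannot be told apart, since the group differs in both, and brightness may itself follow the RNA content of the cells, which was not tested. An action of DAPT through Notch stays open, as Notch targets were not called as a list (median 0.04, adjusted p = 0.55) and HES1 rose by 0.52.

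CDH17 and SI fell together without DAPT, by 1.75 and 1.15 on the log2 scale. Fewer intestinal cells would lower the other genes of the mid and hindgut list too, and their median was 0.12, with TFF3 at -0.41 (adjusted p = 0.070), CDX2 at 0.12 and ANXA13 and VIL1 called higher, by at least 0.59 and by 0.26. The call of ANXA13 was lost with the series matrix values. That of VIL1 (adjusted p = 0.042) was lost without base replicates 1, 2 or 3 (0.078, 0.18 and 0.060). It was also lost without replicates 1, 2 or 3 of the group without DAPT (0.13, 0.13 and 0.078). CDX1, LGR5, OLFM4 and ANXA13 lay near background in base (4.38, 4.40, 4.55 and 4.28), where no fall could show. Only CDX2, VIL1 and TFF3 had room to fall, so the median does not settle whether intestinal cells were fewer. A change within the cells, such as in the regulation of the CDH17 and SI genes by Notch, is open too, and no test here reaches it.

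Transcripts of liver proteins were present on the hESC arrays, most on replicate 3, with AFP at 21.9%, APOA1 at 6.02%, ALB at 5.83% and APOC3 at 2.17% of their base signal. RNA of day 6 cells is argued against as the source, since genes that rose at least 10-fold from day 6 to day 12 stood at 81.8% of their liver bud signal on hESC replicate 3, and genes that rose under 2-fold stood at 3.63%. RNA of day 12 cells may be a source of the signal of the 33 genes, which followed base (Spearman 0.894), with medians of 2.01% and 2.41% of base for those same sets of genes. AFP, ALB and APOA1 were not among the 33 genes, and whether their larger shares come from another source or from a compressed signal of the brightest probes was not tested. Hepatic cells arising in the hESC cultures stay open and were not tested.

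In each comparison, no other of the 35 splits of its 8 arrays into 4 and 4 gave as many called genes as the real one. That share of 2.86% is the smallest that 35 splits give, and it was not adjusted over the 8 comparisons. Mixed splits also add the group difference to the spread of the fit, which lowers their counts. The real split thus ranked first, which does not exclude chance. It says nothing of differences between cultures, since replicates may be technical. The real counts and the highest of the other splits were 6791 and 4475 for endoderm, 6776 and 5184 for the liver bud, 6734 and 2109 for base against the liver bud and 7918 and 2793 for base against hESC. They were 1634 and 750 without DAPT, 170 and 8 without forskolin, 124 and 11 without AAP and 3249 and 2 without insulin.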

How the results depend on the processing

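The fits with array brightness as a covariate and without the day 12 arrays under 15000 detected probes were chosen only after the data were seen. The 4 stage comparisons and that of insulin stayed within 1.5 times their count under every setting but the 2-fold minimum, and with 1 array left out they ran from 6277 to 6887 (endoderm), 6209 to 7005 (liver bud), 6329 to 6560 (base against liver bud), 7561 to 7702 (base against hESC) and 2823 to 3002 (without insulin). Asking for a 2-fold change gave 1771, 1747, 1832 and 3022 genes for the stages and 27, 12, 1 and 367 without DAPT, forskolin, AAP and insulin. With no background correction these 2-fold counts were 702, 744, 839 and 1521 for the stages and 2, 4, 0 and 125 for the withdrawals. With the series matrix values the withdrawals gave 79, 23, 11 and 562. Without DAPT the count of 1634 became 3120 under median scaling, 1024 with the series matrix values, 721 with the brightness covariate, 1004 without arrays of low detection and 814 to 2228 with 1 array left out. Without forskolin the 170 became 111 with the series matrix values, 503 with the covariate, 44 with only the 8 arrays, 77 without arrays of low detection and 105 to 173 with 1 array left out. Without AAP the 124 became 47 under median scaling, 79 with the series matrix values, 313 with the covariate, 20 with only the 8 arrays, 58 without arrays of low detection and 68 to 153 with 1 array left out. Fits of 8 arrays or without arrays rest on fewer samples; for the other settings the cause was not tested. DAPT against forskolin and against AAP withdrawal differed in 1612 and 1566 genes with the series matrix values, in place of 2455 and 2492.

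Among named genes directions turned for POU5F1 at day 2, which was -0.23 with the mean of its probes and -0.48 with the stricter filter, other probes than the dim one used, and for VIL1 at day 12, -0.037 under median scaling, where the cause was not tested. Among all genes, called genes turned under median scaling in base against liver bud (118) and against hESC (283), with the covariate (1 and 20), with the stricter filter (1 in each) and with the mean of probes in the 4 stage comparisons (7 to 11 each). Of 363 values of named genes, median scaling left 340 with the same call, 17 weaker and 5 stronger, the series matrix values 337, 24 and 2, the covariate 339, 15 and 9, only the 8 arrays 339, 23 and 1, no background correction 358, 3 and 2, no filter 361, 2 and 0, and the mean of probes 361, 0 and 1. Of 2904 values with 1 array left out 2814 kept their call. Of 65 list values, called or not, an estimated correlation left 57 with the same call and 8 weaker, fry 61 the same and 4 stronger, and median scaling 63 the same and 2 weaker. The replicate number as a block gave 1711 genes without DAPT, 171 without forskolin, 124 without AAP and 3304 without insulin. Deviations of arrays with the same number correlated from -0.73 to 0.65, and 8 of 32 arrays correlated best with their own number. In no comparison were all 4 correlations above 0.1, so the numbers were not taken as pairs, though for liver bud against endoderm (0.65, 0.22, -0.021 and 0.65) and without AAP (0.29, 0.30, 0.017 and 0.36) 3 of 4 arrays correlated best with their own number. A block by BeadChip was not run because the files name no chip. Signal over background limits dim genes such as PCK1, CREM and POU5F1, whose changes the offset shrinks, and AFP, the brightest probe at day 12, has a level fixed by its rank.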

Other observations

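The test of the cell cycle list was chosen only after the result was seen, and that of all genes before. At day 2 WNT targets rose in 9 of 15 cases and fell in 1 (median 0.32, adjusted p = 0.0011), with DKK4 at least 8.35-fold, APCDD1 7.57-fold and AXIN2, a feedback inhibitor of WNT, 3.05-fold up. Glucocorticoid and metallothionein genes fell in 10 of 16 cases and rose in 3 (median -1.04, adjusted p = 0.0012), where MT1E fell by 4.38, SGK1 fell by 2.93 and MT1X fell by 2.85. At day 6 neural ectoderm genes fell in 8 of 12 cases (median -1.09, adjusted p = 0.0003), among them OTX2, of the anterior embryo, which fell by 4.93. Genes of laminins and other basement membrane proteins rose in 11 of 16 cases (median 0.61, adjusted p = 0.00012), with FREM2 17.9-fold and LAMB1 8.42-fold up. Retinoic acid targets rose in 9 of 13 cases and fell in 2 (median 0.74, adjusted p = 0.0014), with MEIS2 at least 20.7-fold, MEIS1 10.7-fold and HOXB2 at least 4.54-fold up.

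At day 12 acute phase and STAT3 targets rose in 17 of 20 cases with none lower (median 1.42, adjusted p = 6.2e-10). HAMP rose 32.6-fold, haptoglobin HP 30.9-fold, the factor CEBPD, of the acute phase, 27.2-fold and the protease inhibitor A2M 25.7-fold. Fatty acid synthesis genes, which fell without insulin, rose in 14 of 19 cases and fell in 2 (median 0.67, adjusted p = 5.2e-05), with ACSS2 11.9-fold, MLXIPL 4.66-fold and FASN 3.03-fold up.

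DKK1 ran from 4.36 in hESC over 6.93 at day 2 and 11.06 at day 6 to 4.53 in base, and it read 6.69 without insulin, 6.73 without forskolin, 4.54 without DAPT and 4.57 without AAP. SI, chosen after its values were seen, read 7.54 in base, 6.38 without DAPT, 8.05 without forskolin, 7.65 without AAP and 8.01 without insulin.

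One hypothesis is that cells without insulin advance more slowly from day 6 to day 12. Of 939 genes that were called without insulin and changed at least 2-fold from day 6 to the other 3 withdrawals, 76.9% moved back towards day 6. These were 465 of 612 genes that had risen and 257 of 327 that had fallen, among them FST and DKK1. Without AAP the share was 85.1% of 74 genes, without forskolin 60.6% of 71 and without DAPT 57.2% of 425, so a return towards day 6 is not particular to insulin. The cell cycle genes, which fall from day 6 to day 12, argue against slower progress as the whole account, since their median without insulin was -0.31, further from day 6, with 13 of 27 called lower and 1 higher, though the call of the list was lost with an estimated correlation (adjusted p = 0.077). Slower progress may account for a part of the genes, and direct effects of insulin on FOXO and SREBF1 targets stay open beside it.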
